A study of Staphylococcus aureus with 8 samples.

How the data were processed

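The series holds 8 RNA libraries from Staphylococcus aureus strain NCTC 8325. Cultures were started at 34000 bacteria per mL and grown for 20 h at 37 °C and 200 rpm in B medium with 100 µM of a compound in DMSO, or with DMSO alone, per the labels' protocols. The series design gives 2 biological replicates per treatment, so the 8 libraries come from 4 cultures, each with a library labelled minus TEX and a library labelled plus TEX. TEX is a 5′-monophosphate-dependent exonuclease that digests processed RNA and leaves primary transcripts with a 5′ triphosphate. The 4 groups of 2 libraries were taken from the sample titles. The treatment protocol calls the compound by the number 3, while the count columns carry the number 1, and the columns were matched to the samples by treatment, TEX label and replicate, because the deposited table is itself a comparison of DMSO with the compound of these columns. Whether both numbers mean the same compound is not given in the sources used here.

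The deposited table gives estimated counts per annotated feature in sense and in antisense orientation, per the file headers. Between 24.8% and 45.1% of the coding sequence values of a library were not whole, so reads shared by several features had been divided. The aligner and the counting program are not given in the sources used here. The authors also deposited log2 fold changes and p-values with their adjusted values for the libraries labelled minus TEX, and DESeq 1.12.1 is named in the submitters' processing notes. Another 4 count columns in the table carry the name of another compound, match no sample used here and were left out of every step. The table has 5688 entries, each a feature in sense or antisense orientation. All 5688 matched a gene of the reference table of assembly ASM1342v1 by protein accession or gene identifier, and 5686 had the same coordinates there, so coordinates are chromosome positions of that assembly. For 53 coding sequences the product was read from another column of the same table.

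The counts were rounded to whole numbers. The 2767 coding sequences in sense orientation were tested. The 16 rRNA genes and 61 tRNA genes stayed out of library sizes and tests because near-identical copies share reads. Compound was compared with DMSO within each TEX label by edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filterByExpr filter and the quasi-likelihood F-test. Adjusted p-values follow Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Normalised values in CPM (counts scaled to library size) are TMM-scaled over all 8 libraries. Antisense counts were tested in the same way with the library sizes of the sense coding sequences. After the data were examined, further comparisons were added. The effect of the TEX label within each treatment was tested with edgeR, without pairing the 2 libraries of a culture. The log2 CPM of the minus and plus TEX library of each culture (prior count 2) was averaged and tested with limma 3.58.1 with a trend, and the difference of the same pair was tested between treatments. The mean over both libraries of a culture has the same value whichever of them is called minus or plus.

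Lists of genes were fixed before the data were examined: 21 lists, of which 312 members were found and 43 were not. The 20 lists with at least 5 measured members were tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. The names given below follow a rule fixed at the same time. It took the 12 largest rises and the 12 largest falls among called genes with a mean of at least 20 CPM and no overlap between compound and DMSO libraries, up to 4 members of each list with the smallest p, a fixed set of virulence and stress genes, and operon neighbours of the first kind. One gene of the fixed set, mgrA, was not found because its product, a hypothetical protein, did not match the words required. The rule was applied to the comparison of libraries labelled minus TEX and to the added mean per culture, and named 167 genes.

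Alternatives changed the scaling (RLE, library totals alone, upper quartile), the tool (DESeq2 1.42.0), the filter (none, or a mean of at least 50 counts), the features kept, the null (a 1.5-fold change) and the replicate number as a block, and left out each library in turn, which assumes that a lone library varies like the other groups. For sense genes the scaling was computed again on the genes that each filter kept. Alternatives chosen after seeing the data were the pairing of unlike TEX labels and all those of the added comparisons. The tests were tried on simulated counts drawn from the real means and library sizes. Each simulation gave all genes and libraries the same preset spread, and drew the 2 libraries of a culture independently. The false calls given here therefore do not measure the error rate in the real data. For the libraries labelled minus TEX, edgeR called 7 of 65 genes changed 2-fold, 46 of 70 changed 4-fold and 64 of 65 changed 8-fold, with 4 false calls among 121, over 2117 genes. For those labelled plus TEX it called 34 of 65, 57 of 63 and 71 of 72, with 3 false calls among 165, over 2496 genes. For the mean per culture, limma called 10 of 53, 53 of 65 and 80 of 82 at the same sizes, with 3 false calls among 146, over 2535 genes. The p-values rest on 2 cultures per treatment. Tables were made in Python 3.11.15 with pandas 2.3.3, and plots with matplotlib 3.10.9. Limits from counts of 0 use 3 counts over both libraries of the group and cover counting error only.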

Results

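The series asked how the transcriptome of Staphylococcus aureus changes under an antivirulence lactone. RNA was sequenced from 2 cultures grown with 100 µM compound and 2 grown with DMSO, each as a library labelled minus TEX and a library labelled plus TEX. Total counts ran from 4514955 to 51688015 per library, and rRNA took 91.4% to 95.4% of the counts in sense orientation. Sense coding counts were 1055140 and 955981 in the DMSO libraries labelled minus TEX, and 1052101 and 988339 in those labelled plus TEX. The compound libraries were shallower, with 140829 and 77601 sense coding counts labelled minus TEX and 196101 and 239463 labelled plus TEX. The DMSO libraries were thus 9.21 times and 4.69 times deeper in the minus and plus TEX comparison. The delta-hemolysin gene hld, which lies within the agr effector RNA, took 17.4% ± 0.0195 of sense coding counts in DMSO libraries labelled minus TEX and 28.4% ± 3.52 in compound libraries of that label (SD, n = 2). In the libraries labelled plus TEX hld took 15.8% ± 1.92 with DMSO and 28.6% ± 0.792 with compound (SD, n = 2).

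The TEX label split the genes in opposite ways in the 2 treatments. In DMSO cultures 703 genes were higher and 675 lower in the libraries labelled plus TEX than in those labelled minus TEX, of 2560 tested with edgeR. This test did not pair the libraries of a culture. Paired by culture, 1520 genes were called with DMSO and 825 with compound. In compound cultures 384 were higher and 457 lower, of 1472, and that total of 841 was 415 without the compound library of replicate 1 labelled minus TEX and 403 with DESeq2. Of 707 genes called in both treatments, 706 had opposite signs, and the log2 changes correlated at r = -0.886 across 1472 genes, which are not independent replicates. The agr regulator gene agrA had a mean of 7858 ± 891 CPM labelled minus and 2763 ± 279 CPM labelled plus TEX with DMSO, and 5625 ± 589 and 12394 ± 1237 CPM with compound (SD, n = 2). The difference in the TEX effect between treatments was called by limma for 1267 of 2507 genes, 592 higher and 675 lower in compound. Without either DMSO culture that count was 0, with 942 and 784 genes at an unadjusted p under 0.05, while edgeR over all 8 libraries called 1417.

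**Figure D1:**
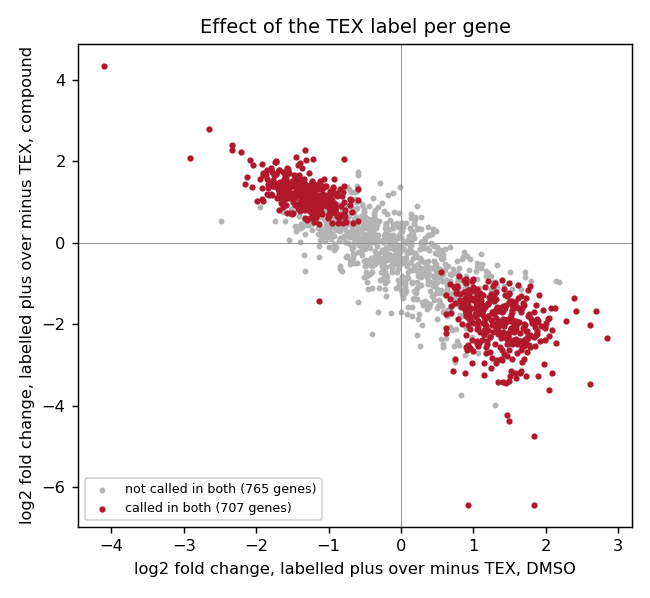
Each point is a gene, with the log2 fold change of libraries labelled plus over minus TEX in DMSO cultures on the horizontal axis and in compound cultures on the vertical axis. Red points are the 707 genes called in both, of which 706 lie in the quadrants of opposite sign.

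Across 2507 genes, mean log2 CPM of the compound libraries labelled minus TEX correlated with DMSO libraries labelled plus TEX at r = 0.923 and with those labelled minus TEX at r = 0.812. The compound libraries labelled plus TEX correlated with DMSO libraries labelled minus TEX at r = 0.933 and with those labelled plus TEX at r = 0.813. The same order held in every pair of single libraries, from 0.843 to 0.906 against 0.712 to 0.831 in the first case and from 0.888 to 0.918 against 0.754 to 0.814 in the other. Libraries are therefore named by their label throughout.

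Compound against DMSO in the libraries labelled minus TEX was the comparison for which the authors deposited their own test. The gamma-hemolysin genes hlgA (positions 2489229 to 2490158), hlgB and hlgC, which encode bicomponent leukotoxins, fell by 5.86, 4.06 and 3.31 on the log2 scale. The alpha-toxin gene hla, at positions 1076413 to 1077372, went from 879 ± 158 CPM with DMSO to 71.9 ± 3.37 CPM with compound (SD, n = 2), a log2 change of -3.49 ± 0.32 (SE, edgeR adjusted p = 1.2e-15). The immunoglobulin-binding proteins fell as well, sbi by 3.60 and spa, which encodes protein A, by 3.49. The fibrinogen-binding protein gene efb fell by 4.46, and the chaperone gene clpB fell by 3.63 (edgeR adjusted p = 1.02e-17). In all, edgeR called 438 genes higher and 496 lower of 2276, and the median log2 change was 0.05.

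Among the rises in the libraries labelled minus TEX were the urease genes ureB, ureC and ureA, with log2 changes of 3.96, 1.67 and 1.84. SAOUHSC_02234, annotated as a repressor-like protein, rose by 3.68 ± 0.42 (SE), and SAOUHSC_A00354, a hypothetical protein, by 2.90 ± 0.25. The coagulase gene coa rose by 2.38 ± 0.62 (edgeR adjusted p = 0.0014). SAOUHSC_01507, SAOUHSC_02662 and SAOUHSC_02528 had 0 counts in both compound libraries and were at least 5.27-fold, 4.67-fold and 4.49-fold lower. The calls rest on few counts in compound libraries: hlgA had 4 and hla 19 counts over both. Scaled by library totals alone, the median moved to 0.61 and the calls to 687 higher and 262 lower. Without compound replicate 1 the count of calls was 597, and DESeq2 called 549. Leaving out DMSO replicate 2 ended the calls of ureB (edgeR adjusted p = 0.108), ureA (0.289) and coa (0.085), and ureA was also lost without compound replicate 1 (0.345) or DMSO replicate 1 (0.0775).

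In the libraries labelled plus TEX the same toxin genes were lower again, but much of the remaining response had the other sign. hlgA, hlgB and hlgC fell by 4.61, 3.32 and 2.99 on the log2 scale, hla by 1.88 ± 0.34 (SE, edgeR adjusted p = 2.71e-07) and sbi by 3.99. The agr genes agrB, agrC and agrA, which encode the quorum-sensing system, rose by 1.76, 2.14 and 2.19, and sarA, a global virulence regulator, by 2.34. In the libraries labelled minus TEX the agr genes had log2 changes of 0.04, -0.34 and -0.38, none called. There agrB was called higher with library totals alone (0.64, edgeR adjusted p = 0.0215) and with a mean of at least 50 counts (0.85, 0.00278), agrC and agrA with neither. Under that label sarA fell by 0.75. Its call was lost without compound replicate 2 (log2 change -0.63) or with library totals alone (edgeR adjusted p = 0.392). With a mean of at least 50 counts the log2 change of sarA was 0.044. ureB, ureA and ureC fell by 3.10, 4.20 and 1.54, and without compound replicate 1 ureB and ureC were not called (edgeR adjusted p = 0.155 and 0.0584). The hypothetical SAOUHSC_02018 rose by 5.14 ± 0.28 labelled plus TEX and fell by 3.53 ± 0.36 labelled minus TEX.

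edgeR called 566 genes higher and 640 lower of 2439 in the libraries labelled plus TEX, with a median log2 change of -0.30, which was not subtracted from the values given. Of 678 genes called in both comparisons, 642 had opposite signs, 15 were higher in both and 21 lower in both, and the log2 changes correlated at r = -0.554 across 2263 genes. Scaled by library totals alone, the median was -1.65 and the calls 90 higher and 1667 lower. With that scaling SAOUHSC_02234, which rose by 1.00, had a log2 change of -0.34, and it was not called without compound replicate 1 (edgeR adjusted p = 0.567) or DMSO replicate 1 (0.0717). Without compound replicate 1 there were 747 calls, without compound replicate 2 there were 786, and DESeq2 called 775.

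**Figure D2:**
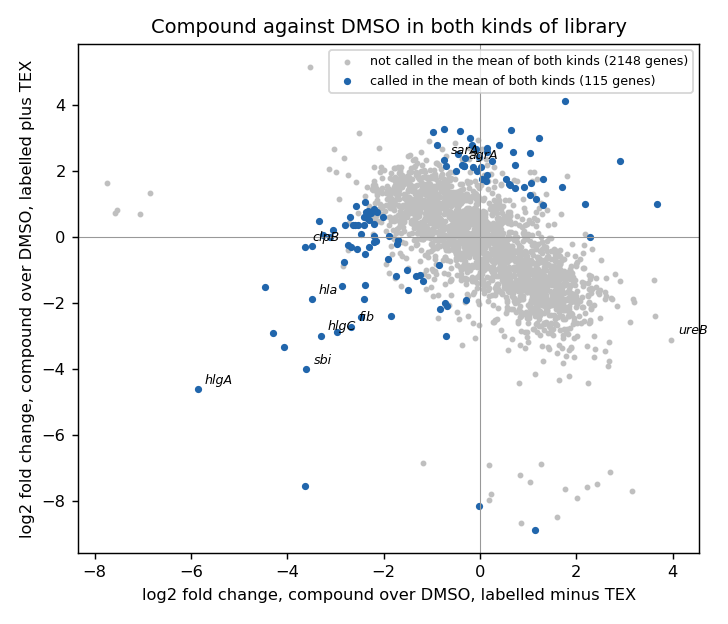
Each point is a gene, with the log2 fold change of compound over DMSO in libraries labelled minus TEX (horizontal) and labelled plus TEX (vertical). Blue points are the 115 genes called in the mean of both library kinds per culture, and hlgA, hlgC, hla, sbi and fib lie in the quadrant of falls in both.

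The mean of both library kinds per culture, a comparison added after the data were examined, gave the changes that do not depend on which library of a culture is called minus or plus. Toxin genes fell: hlgA by 5.08 ± 0.28 (SE, limma adjusted p = 1.6e-06), hlgB by 4.14 ± 0.42, hlgC by 3.11 ± 0.27 and hla by 2.74 ± 0.27, which is 33.7-fold, 17.6-fold, 8.64-fold and 6.69-fold. Genes of surface and secreted binding proteins fell as well, sbi by 3.86 ± 0.48, efb by 2.80 ± 0.48, fib by 2.63 ± 0.28, eap by 2.23 ± 0.43 and spa by 1.88 ± 0.22. Reads of hlgC and hlgB were divided with other features in 6 and 7 of the 8 libraries. The log2 change of spa was -3.49 labelled minus TEX and -0.28 labelled plus TEX, and the TEX effect on it differed between treatments (limma adjusted p = 0.00964). The same held for efb (0.0192), while for hla, hlgA, hlgB, hlgC, sbi, fib and eap no such difference was called, with adjusted p from 0.116 for hla to 0.997 for hlgB. SAOUHSC_02167, SAOUHSC_00717 and SAOUHSC_00716, hypothetical proteins, fell by 2.97, 3.84 and 2.06. The sensor kinase gene saeS and the response regulator gene saeR, next to SAOUHSC_00716, had log2 changes of -1.62 ± 0.46 and -1.16 ± 0.32 and were not called (limma adjusted p = 0.0711 and 0.0668), though both were without compound replicate 1 (0.0386 and 0.000675) or compound replicate 2 (3.98e-08 and 0.017), with library totals alone (0.00917 and 0.00649) and by edgeR on summed counts (0.00826 and 0.0315). Without DMSO replicate 2 the calls of sbi (limma adjusted p = 0.131), SAOUHSC_00717 (0.0875), SAOUHSC_00716 (0.285), efb (0.265) and eap (0.413) ended, the last 3 also without DMSO replicate 1 (0.0622, 0.175 and 0.151).

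The regulators agrB, agrC and agrA rose by 0.86 ± 0.22, 0.87 ± 0.20 and 0.87 ± 0.20 in that mean, and sarA by 0.76 ± 0.17 (SE). With the replicate number as a block none of them was called (limma adjusted p = 0.113, 0.0608, 0.0673 and 0.0732). The agr calls ended when either compound culture was left out, with limma adjusted p of 0.0873 and 0.207 for agrA, 0.0689 and 0.184 for agrC, and 0.169 and 0.339 for agrB, and also without a filter (0.075, 0.075 and 0.109), where the log2 changes were 0.83 to 0.84. That of sarA ended without compound replicate 1 (0.105) or DMSO replicate 1 (0.0515). hld had a log2 change of 1.13 ± 0.54 and was not called (limma adjusted p = 0.298), with 0.14 labelled minus TEX (edgeR adjusted p = 0.832) and 2.19 labelled plus TEX (1.59e-12). It was called in the mean with library totals alone (0.0138), a mean of at least 50 counts (0.0272) and edgeR on summed counts (0.0107). Labelled minus TEX, hld was called higher with a mean of at least 50 counts (log2 change 0.93, edgeR adjusted p = 0.00374). Other rises were SAOUHSC_A00354 by 2.55, SAOUHSC_02234 by 2.12, SAOUHSC_00561 by 2.09, SAOUHSC_01285, annotated as a glutamine synthetase repressor, by 1.88, the phage Cro-like gene SAOUHSC_02083 by 1.66 and the DNA primase gene SAOUHSC_01663 by 1.52. SAOUHSC_02234 was not called without DMSO replicate 1 (0.063) or DMSO replicate 2 (0.0511), nor SAOUHSC_00561 without compound replicate 1 (0.0896) or compound replicate 2 (0.134). The redox-responsive regulator gene spxA rose by 1.15 ± 0.18. The genes rot, codY, sigB, asp23 and coa had log2 changes of 0.33, 0.35, -0.13, 0.13 and -0.41, and clpP, nuc, aur and sspA of -0.62, -1.05, -0.69 and -0.33, none of them called. Leaving out compound replicate 1 brought clpP under the threshold (0.0203), and leaving out compound replicate 2 did so for nuc (0.0332). Library totals alone did so for clpP (0.000636) and aur (0.0127), and edgeR on summed counts for rot (0.000116) and codY (0.0148).

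limma called 47 genes higher and 68 lower of 2507 in the mean per culture, with a median log2 change of -0.18. The split was 59 higher and 47 lower with RLE, 59 and 54 with the upper quartile, and 38 and 379 with library totals alone, whose median was -0.50. edgeR on counts summed per culture called more genes higher than lower, 172 and 82. Leaving out compound replicate 1 gave 87 higher and 309 lower, compound replicate 2 gave 90 and 294, and DMSO replicate 2 gave 28 and 17. Of the 33 called genes of this text, 16 stayed called in each of the 4 cases of a culture left out. Among those were hla, hlgA, hlgB, hlgC, fib, spa and clpB.

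**Figure D3:**
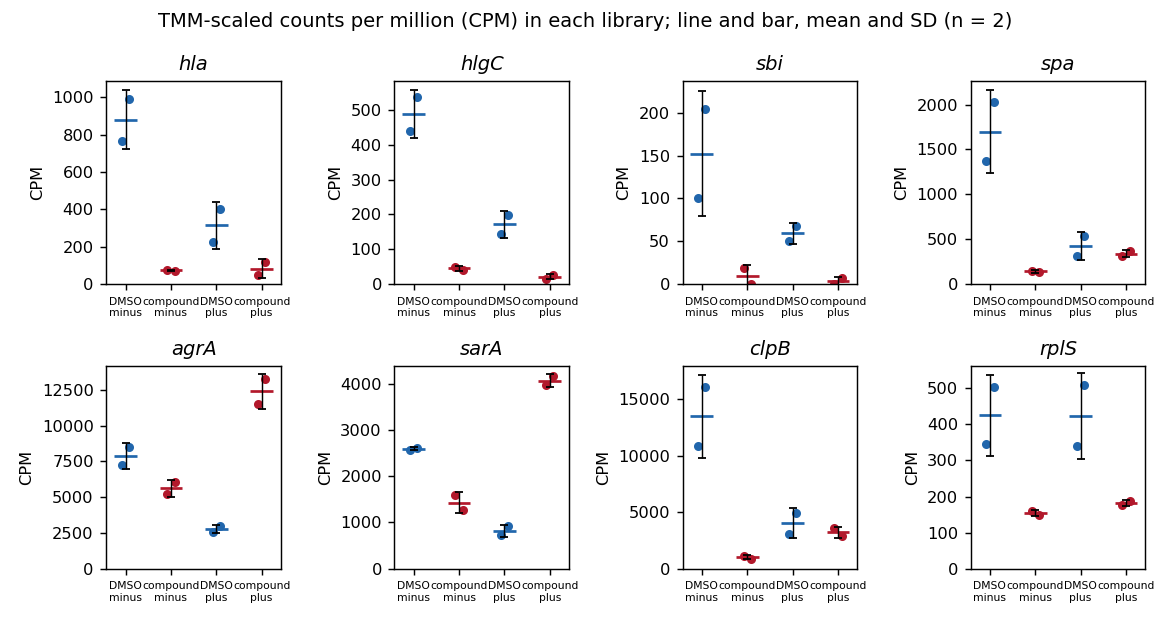
Points are single libraries, coloured by treatment, with the mean as a line and the SD as a bar (n = 2), in TMM-scaled CPM. hla is lower with compound under both labels, from 879 to 71.9 CPM labelled minus and from 314 to 81.2 CPM labelled plus TEX, while agrA goes from 7858 to 5625 CPM labelled minus and from 2763 to 12394 CPM labelled plus TEX.

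Of the lists fixed beforehand, 7 were called in opposite directions under the 2 labels. All 12 TCA cycle genes measured fell in the libraries labelled minus TEX, among them icd by 2.02 and sdhB by 1.13, and 11 of 12 rose in those labelled plus TEX, sdhB by 2.32 and icd by 0.62. With a mean of at least 50 counts sdhB labelled minus TEX was -0.32 and not called (edgeR adjusted p = 0.181). The change of icd labelled plus TEX was -0.72 with library totals alone, and without compound replicate 1 or compound replicate 2 it was not called (edgeR adjusted p = 0.222 and 0.204). Oxidative stress genes gave 10 falls of 11 and then 9 rises of 11. Of 14 virulence regulator genes 9 fell labelled minus TEX, and labelled plus TEX 9 rose and 1 fell. Branched-chain amino acid synthesis (7 of 8 rose, then 6 of 8 fell), capsule (9 of 15 rose, then 9 of 16 fell), purine synthesis (4 of 11 rose, then 7 of 13 fell) and urease (3 of 5 rose, then 4 of 7 fell) went the other way. camera called these 7 lists under both labels, with an adjusted p between 1.03e-06 and 0.0458. With an estimated correlation the adjusted p was 0.366 labelled minus TEX and 0.511 to 0.545 labelled plus TEX, so no call held. The call of urease labelled minus TEX ended without compound replicate 1 (0.143) or compound replicate 2 (0.0875), and that of purine synthesis without DMSO replicate 2 (0.0605).

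Of the 11 lists camera called in the libraries labelled minus TEX, the other 4 were glycolysis (5 of 10 fell), cytolytic toxins (4 of 5 fell), heat shock and Clp proteases (12 of 16 fell) and ribosomal proteins (26 of 47 fell), which also had an adjusted p of 0.366 with an estimated correlation. Another 5 members of the cytolytic toxin list were not found. Adjusted over the list alone, the counts labelled minus TEX were 8 for branched-chain amino acid synthesis, 27 for ribosomal proteins and 10 for virulence regulators, and the same for the other called lists, and labelled plus TEX 7 for branched-chain amino acid synthesis and the same for the others. Lists that camera did not call there were secreted enzymes (8 rose and 2 fell of 16, adjusted p = 0.0963), pyrimidine synthesis (4 and 1 of 6, 0.0963), phage genes (11 and 4 of 27, 0.0963), surface adhesins and immune evasion (2 and 7 of 14, 0.0605), sigma B and its regulon (1 and 3 of 6, 0.131), cell wall stress and autolysis (0 and 4 of 17, 0.141), aminoacyl-tRNA synthetases (4 and 3 of 20, 0.39), iron acquisition (2 and 0 of 6, 0.591) and fermentation and nitrate respiration (5 and 4 of 14, 0.916). The arginine deiminase pathway, with 4 members found, was not tested.

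In the mean of both library kinds camera called 4 of 20 lists, all lower, and none of them with an estimated correlation (adjusted p = 0.954 for all 4). The cytolytic toxin list had 5 members found and 5 not found. Of the 5 measured 4 fell, hla and the neighbouring hlgA, hlgB and hlgC (camera adjusted p = 1.97e-06, and 0.954 with an estimated correlation). Labelled plus TEX 4 fell and hld rose, and the list was not called (camera adjusted p = 0.103). Of 16 heat shock and Clp genes 6 fell, among them clpB by 1.98, mcsA by 1.66, mcsB by 1.62 and grpE by 1.11, and 1, spxA, rose. Labelled plus TEX the changes of clpB, mcsA, mcsB and grpE were -0.30, 0.07, 0.0011 and 0.36, none called, and the list had 6 rises and 1 fall (camera adjusted p = 0.103). With library totals alone these 4 were called lower, at -1.63, -1.26, -1.33 and -0.98 (largest edgeR adjusted p = 5.39e-07). clpB was also called without DMSO replicate 1 (-0.55, 0.00157), and grpE was called higher without DMSO replicate 2 (0.58, 0.00262). Ribosomal proteins gave 10 falls of 51, such as rplD by 1.56, rplB by 1.33, rplS by 1.27 and rplK by 1.18. Labelled plus TEX that list had 10 rises and 6 falls of 49 (camera adjusted p = 0.422), with falls of rplD by 1.61 and rplS by 1.19 (edgeR adjusted p = 0.00307 and 0.000168) and with rplK at 0.35 and rplB at -0.66, neither called. rplD was not called there without compound replicate 1 (0.077) or with DESeq2 (0.052). rplK was called higher without DMSO replicate 2 (0.71, 0.0199) and lower with library totals alone (-0.98, 0.000822). rplB was called lower without DMSO replicate 1 (-0.85, 0.0154), with library totals alone (4.71e-09), with a mean of at least 50 counts (0.0394) and with rRNA and tRNA kept (0.0465). Surface adhesins and immune evasion gave 5 falls of 15 (adjusted p = 0.0301), and labelled plus TEX 3 rises and 7 falls of 14 (0.289). Adjusted over the list alone, 4, 8, 14 and 5 members fell. fry called 0 lists, and 4 had an unadjusted p under 0.05. The heat shock call ended without compound replicate 2 (camera adjusted p = 0.139), and the ribosomal and adhesin calls without DMSO replicate 2 (0.0988 and 0.37), while 7 lists were called without DMSO replicate 1. Without DMSO replicate 2 rplK, rplB, rplS and rplD were not called (limma adjusted p = 0.172, 0.187, 0.122 and 0.415), nor rplD without DMSO replicate 1 (0.0504).

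Of the TCA cycle genes icd and sucC fell by 0.73 and 0.96 in the mean, and both calls ended with RLE scaling, with limma adjusted p of 0.065 and 0.0708. Without compound replicate 2 or DMSO replicate 2 neither was called (icd 0.141 and 0.135, sucC 0.0637 and 0.467), nor icd without compound replicate 1 (0.0839). The other 16 lists were not called in the mean, with camera adjusted p from 0.354 for aminoacyl-tRNA synthetases to 0.949 for phage genes. Virulence regulators gave 4 rises of 15 (0.534), and fry's mixed test, which counts changes in either direction, gave them an unadjusted p of 0.000129.

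**Figure D4:**
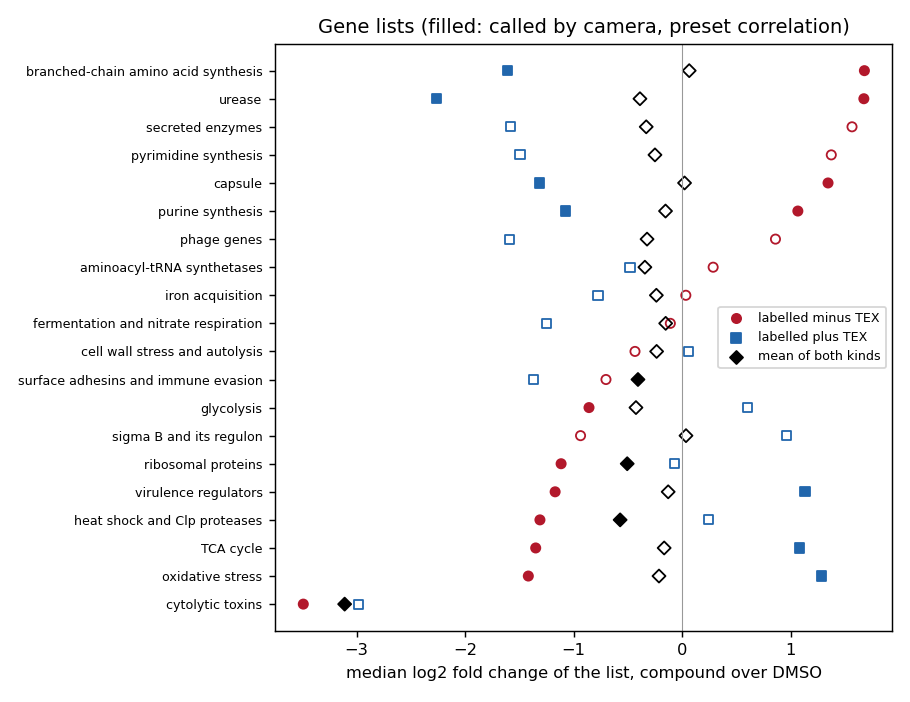
Each line of the plot is a gene list, with the median log2 fold change of compound over DMSO labelled minus TEX (circles), labelled plus TEX (squares) and in the mean of both kinds (diamonds). Filled symbols are called by camera at the preset correlation, and cytolytic toxins lie at -3.49, -2.99 and -3.11.

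Antisense reads over coding sequences took 9.79% ± 2.16 of coding counts in DMSO libraries labelled minus TEX and 20.7% ± 3.74 in those labelled plus TEX (SD, n = 2). The order was opposite with compound, with 23.2% ± 0.0047 labelled minus and 14.3% ± 2.43 labelled plus TEX. In the libraries labelled minus TEX edgeR called the antisense reads of 92 genes higher and 13 lower with compound, of 1366, with a median log2 change of 1.26. In those labelled plus TEX it called 29 higher and 662 lower of 2057, with a median of -1.51. Of 56 genes called under both labels, 55 had opposite signs. The minus TEX count was 7 without compound replicate 1, 4 without compound replicate 2 and 483 without DMSO replicate 1.

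The authors' deposited table for the libraries labelled minus TEX has 1 coding sequence higher and 105 lower in sense orientation at an adjusted p under 0.05. The one that rose in the authors' deposited table was SAOUHSC_02234, at a log2 change of 3.46, and the lowest was hlgA at -6.17. All 105 were called lower here in the libraries labelled minus TEX, 35 were called lower in the mean per culture, and in the libraries labelled plus TEX 5 were called lower and 79 higher.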

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

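The test of the TEX difference between treatments, the comparison of antisense shares, the pairing of unlike labels and the comparison of rRNA and tRNA shares were chosen only after the results were seen. The effect of the TEX label differed between compound and DMSO cultures for 1267 genes by a limma test of the difference itself, and for 37 of the 57 genes tabulated for the text out of the 167 named by the rule. The share of antisense reads differed by 10.951 percentage points between plus and minus TEX in DMSO cultures and by -8.8937 percentage points in compound cultures, each in the same direction in both cultures. That difference between treatments was not tested.

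The pattern weighed first is that 706 of 707 genes called in both treatments changed with the TEX label in opposite directions. The greater depth of the DMSO libraries is argued against: with the DMSO counts thinned to the depth of the compound libraries in 10 draws, the correlation of the TEX effects was -0.836 at the median, between -0.849 and -0.824. A candidate explanation is that the minus and plus labels are exchanged in the libraries of 1 treatment. TEX effects on antisense reads, which took no part in the pattern, correlated between treatments at r = -0.727 over 372 genes. Antisense and sense reads come from the same libraries. This correlation therefore does not tell an exchange from another cause that acts on whole libraries. Compound libraries set against DMSO libraries of the other label gave 204 and 62 called genes, against 934 and 1206 for like labels. TEX effects of opposite sign lead to fewer calls in unlike pairings whatever their cause. These counts therefore restate the pattern and are no test of an exchange. Which treatment would hold the exchange cannot be told apart. The rRNA and tRNA shares followed the order an exchange in compound would need in 3 of 8 pairs of libraries. These shares lay between 96.6% and 98.3% in every library, so neither label showed a clear loss of such RNA. Their order therefore cannot place an exchange. A change of the RNA 5′ ends by the compound itself stays open and was not tested.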

How the results depend on the processing

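The pairing of unlike TEX labels, and every alternative for the TEX effects and the mean per culture, was chosen only after the results were seen. Of 783 values of single genes in the mean per culture, 678 kept their side of the threshold, 71 lost and 34 gained a call. Of these values 0 changed sign with a call in either setting. Labelled minus TEX these were 739, 53, 14 and 13 of 819, and labelled plus TEX 692, 46, 20 and 20 of 778. In each comparison a gene called in neither setting was counted as kept, whatever its sign. Depth limits the compound libraries, where 77601 sense coding counts were the fewest.

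Labelled minus TEX, 934 genes were called, 549 with DESeq2, 390 with a mean of at least 50 counts and 608 against a 1.5-fold change. The filter at 50 counts left 885 genes to test, and the scaling was computed again on these. Of its 390 calls 279 were shared with the 934. Log2 changes of single genes moved with it, such as agrB from 0.04 to 0.85 and asp23 from -0.94 to -0.17. Labelled plus TEX, 1206 were called and 775 with DESeq2. With TEX labels exchanged the counts were 204 and 62. In the mean per culture 115 were called, 417 with library totals alone, 69 without a filter, 68 at a pseudocount of 0.5, 21 against 1.5-fold and 254 by edgeR on summed counts. The TEX effect in compound cultures had 841 calls and 403 with DESeq2. Leaving out 1 library or culture gave 597 to 836 labelled minus TEX, 747 to 1241 labelled plus TEX, 45 to 396 in the mean, 954 to 1335 for TEX in DMSO, 415 to 673 for TEX in compound, 0 to 1594 for their difference, 4 to 483 for antisense reads, 9 to 11 lists labelled minus TEX and 3 to 7 lists in the mean. The 0 came from limma without either DMSO culture, with 942 and 784 genes at an unadjusted p under 0.05, against 1417 by edgeR over all libraries. Apart from the filter and the null, the cause was not tested.

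For lists labelled minus TEX, camera with an estimated correlation called 0, with 1 at an unadjusted p under 0.05. fry called 9, of which 1 was higher, and lost branched-chain amino acid synthesis (adjusted p = 0.0569), purine synthesis (0.0953) and urease (0.055). With TEX labels exchanged 4 were called, where oxidative stress (adjusted p = 0.974) and virulence regulators (0.415) pointed up instead of down. In the mean, an estimated correlation gave 0 lists, with 0 at an unadjusted p under 0.05, and fry gave 0, with 4. The cause was not tested.

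The replicate number as a block gave 70 genes in the mean, against 115, and 8 for antisense reads labelled minus TEX, against 105. It gave 865 labelled minus TEX, 1160 labelled plus TEX, 1520 and 825 for TEX in DMSO and compound, 1068 for their difference, and 12 and 4 lists. Deviations of same-numbered compound and DMSO libraries correlated at -0.0303 and -0.0266 labelled minus and plus TEX. The 2 libraries of one culture, which do share it, gave 0.204 with DMSO and -0.0242 with compound, so the measure does not show whether the numbers pair the cultures.

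Changes of sign are given here only for genes called in either setting. With TEX labels exchanged these log2 changes turned from the minus TEX comparison: SAOUHSC_02018 1.11, agrC 0.87, agrA 0.84, sarA 0.84, rot 0.77, codY 0.43, asp23 0.13, spxA 1.29 and sdhB 0.80. From the plus TEX comparison, ureB turned to 0.93, SAOUHSC_00917 to 1.03, SAOUHSC_02716 to 0.31, coa to 0.92, sigB to -0.46, clpP to -0.82, mcsA to -1.57, mcsB to -1.52, grpE to -1.04, icd to -0.69 and rpsO to -0.42. Labelled minus TEX with a mean of at least 50 counts, sarA was 0.044, codY 0.0087 and spxA 0.77, and spxA was 0.55 with library totals alone. Labelled plus TEX with library totals alone, SAOUHSC_02234 was -0.34, sigB -0.37, clpP -0.087, asp23 -0.046, mcsA -1.26, mcsB -1.33, grpE -0.98, icd -0.72 and rplK -0.98. The cause was not tested.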

Other observations

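The tests of SaeRS targets, of whole-count genes, of agr genes under unlike labels and of the direction of toxin genes under both labels were chosen only after the results were seen. Several of the genes with values lower under both labels lie close to each other on the chromosome. sbi, hlgA, hlgC and hlgB lie on the plus strand between positions 2487383 and 2492652. fib, efb and hla lie between positions 1070537 and 1077372, with other genes between them, and efb was not called labelled plus TEX (edgeR adjusted p = 0.0781). The sensor kinase gene saeS, saeR, SAOUHSC_00716 and SAOUHSC_00717 lie on the minus strand between positions 699194 and 702165, and saeS had log2 changes of -1.65 and -1.47 under the 2 labels, called in both by edgeR, while saeR was called labelled minus TEX (-1.83) and not labelled plus TEX (-0.50, edgeR adjusted p = 0.346). Reads of saeS were divided with other features in 5 of 8 libraries. Both calls of saeS ended without compound replicate 1 (edgeR adjusted p = 0.275 and 0.333), and that labelled plus TEX without DMSO replicate 2 (0.203).

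The second pattern is the fall of 9 toxin and surface protein genes (hlgA, hlgB, hlgC, hla, sbi, efb, fib, eap and spa), with a median log2 change of -2.80 in the mean per culture. All 9 of 9 were lower under both labels, spa and efb without a call labelled plus TEX, but the genes were chosen for that, so this is no test of an exchange of TEX labels. Thinning of the DMSO counts left 9 of the 9 past the threshold at the median of 10 draws and 8 at the lowest. The greater depth of the DMSO libraries was thus not needed for most of these calls. The compound counts were not thinned, and the genes were chosen for passing this threshold. Thinning therefore does not test whether few counts in the compound libraries bear on the fall. Reads divided between copies are argued against only for the 5 members with whole counts in all 8 libraries, whose median was -2.74 (-3.86 to -1.88). All 9 were chosen for falling, so that median is no test for members with divided reads. Coding length is argued against by a median of -0.19 in 391 genes nearest in length, close to the -0.18 of all genes tested. Lower output of SaeRS, a two-component system known to activate many of these genes, may account for the fall as a hypothesis, but 5 other known targets do not decide it: none was called in the mean, and their median of -0.44 covers coa, fnbB and fnbA, which had log2 changes of 2.38, 1.68 and 0.45 labelled minus and -3.39, -1.83 and -1.30 labelled plus TEX, with nuc, lower under both labels without a call, and emp, tested only labelled plus TEX (-1.44). SAOUHSC_00716 and SAOUHSC_00717, beside saeR and saeS, were called lower in the mean and were not among these 5 genes. Neither call held when each culture was left out in turn.

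The third pattern is the rise of agrB, agrC and agrA in the mean per culture. The pairings of unlike labels gave mean log2 changes of 0.90 and 0.97, which average to about the mean per culture by construction and so are no test of an exchange of TEX labels. Scaling stays open, because the 3 genes had a mean change of 0.51 with library totals alone, against 0.96 with RLE and 0.94 with the upper quartile. Their single-gene SE averaged 0.14 with library totals alone. All 3 were called by limma under each of these scalings. The calls of agrB, agrC and agrA ended without a filter (limma adjusted p = 0.109, 0.075 and 0.075) and at a pseudocount of 0.5 (0.0874, 0.0642 and 0.0639), but their log2 changes of 0.83 to 0.84 and 0.86 to 0.87, with SE of 0.19 to 0.23, stayed close to the 0.86 to 0.87 reported (SE 0.20 to 0.22), so these losses count neither for nor against scaling. The compound as the cause may be one explanation, but the design gives no other test of it.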
